A study of Mus musculus with 8 samples.

How the data were processed

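The samples were primary cardiomyocytes from mouse embryos at embryonic day 18.5, taken from a strain that carries an H2B-eGFP transgene (a fluorescent histone fusion) and grown for 4 days on polydimethylsiloxane, a silicone rubber whose stiffness can be tuned. Per the labels, 4 libraries came from a soft substrate of about 10 kPa and 4 from a stiff substrate of about 150 kPa, and the RNA was total RNA. Groups were taken from the substrate label. The titles give all libraries of a substrate the same name plus a library code, so the replicate numbers 1 to 4 used here follow the order of the samples, which is also the last digit of the codes. Nothing in the labels says that equal digits mark a shared litter, culture or day, and the libraries were therefore compared unpaired. The labels do not say whether the 4 libraries of a substrate came from separate cultures or litters, and p-values measure the spread between these libraries, which may be partly technical.

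The authors deposited a table of coding genes and a table of noncoding genes, both holding raw read counts (whole numbers per gene and library). The submitters' processing notes name FastQC 0.11.2, Bowtie2, TopHat2 2.0.14, HTSeq 0.6.1, TopHat, Cufflinks, DESeq2 and edgeR and the mouse build GRCm38, without saying which step each served. Strand handling, filters and the release of the noncoding annotation are not given in the sources used here. The coding table has 29844 Ensembl genes, of which 29150 matched a symbol; the rows without a symbol hold 0.106% of its counts, and 96.7% of its counts lie in genes that RefSeq lists as protein-coding. The noncoding table has 46475 IDs, none of which matched a symbol in the name tables, so these are given as IDs. Chromosome positions are those of RefSeq genes on GRCm38.p6, the build the labels name.

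Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total of 15, which left 14059 coding and 5747 noncoding genes. Library sizes were scaled by TMM within each table, and stiff was compared with soft by the robust quasi-likelihood F test with substrate as the sole term. P-values were adjusted by the Benjamini-Hochberg method within each table, and an adjusted p under 0.05 counted as a call. Log2 fold changes are stiff over soft, with their standard errors (SE) and unadjusted 95% intervals from the same fit. Levels are TMM-scaled CPM (counts scaled to a common library total) within the gene's own table, so that coding and noncoding levels are on separate scales. The labels name no molecular identifiers, so reads are not independent molecules.

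Before the data were examined, 35 gene lists were fixed from textbook knowledge of the heart, of mechanical signalling and of other cell types that a heart digest can hold. The 30 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 30 lists. A list's library score is the mean over its members of log2 CPM minus the gene's mean over the 8 libraries. Library measures and scores were compared by a two-sided exact permutation test, whose smallest possible p with 4 against 4 is 0.0286. The rule for named genes, fixed at the same time, took called genes first, then up to 4 members of each list by smallest p and up to 2 by highest level, and 6 cardiomyocyte genes for every library. Genes named outside it are said to have been chosen after their values were seen. Some items are not reported here.

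The alternatives fixed in advance were other scaling factors, no filter and a stricter filter of at least 1 CPM in 4 libraries, DESeq2, limma-voom, a test against a fold of 1.2, both tables joined, coding-table factors for the noncoding table, each library left out in turn and a fit with the number as a replicate block. A planned run without mitochondrially encoded and haemoglobin genes would remove no tested gene and was not made. The pipeline was tested on simulated counts drawn from the real means and dispersions with 200 changed genes per table. Of 14059 simulated coding genes, it recovered 50 of 66 changed 4-fold, 16 of 67 changed 2-fold and 2 of 67 changed 1.5-fold, with 6 false calls. Of 5747 simulated noncoding genes, it recovered 13 of 66 changed 4-fold, 0 of 67 changed 2-fold and 0 of 67 changed 1.5-fold, with 0 false calls. In simulated lists of 30 genes, the list shifted 1.5-fold was called and 0 others were. Genes and libraries were drawn independently in all of these simulations, lists included, without variation that real libraries may share. A chi-square comparison of counts found no 2 libraries within sampling noise of each other: chi-square per degree of freedom ran from 45.9 to 233 over the 28 pairs of libraries.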

Results

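Gene expression was measured by RNA sequencing in embryonic mouse cardiomyocytes cultured for 4 days on a soft (about 10 kPa) or a stiff (about 150 kPa) silicone substrate, with 4 libraries per substrate. The comparison asks how substrate stiffness affects messenger and long noncoding RNA in these cells. Coding totals ran from 27646471 to 34693673 counts per library and noncoding totals from 1992836 to 2505251. The coding total was 29370766 ± 1343624 (SD, n = 4) on soft and 31303388 ± 2909516 (SD, n = 4) on stiff. Of 10 library measures, including totals, genes detected and the share of the 10 highest genes, none passed the test between substrates, and the lowest exact permutation p was 0.257 (0.886 after adjustment), for the share of small structured RNAs.

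Cardiomyocyte genes were among the most abundant transcripts on both substrates. Nppa, which encodes atrial natriuretic peptide, had the highest mean level of the coding table over the 8 libraries, with 5588 ± 1498 CPM on soft and 6013 ± 938 CPM on stiff (SD, n = 4 each). The cardiac actin gene Actc1 stood at 5862 ± 3148 CPM on soft and 5408 ± 1620 CPM on stiff. The titin gene Ttn stood at 5061 ± 678 CPM on soft and 5807 ± 2121 CPM on stiff. Myh6, the alpha myosin heavy chain gene at chromosome 14 from 54941921 to 54968017, stood at 4039 ± 2287 CPM on soft and 3765 ± 1072 CPM on stiff. Its neighbour Myh7, the beta heavy chain gene from 54970684 to 54994626, stood at 1283 ± 370 CPM on soft and 1456 ± 705 CPM on stiff. Troponin T (Tnnt2) stood at 2711 ± 892 and 2607 ± 411 CPM, and the B-type natriuretic peptide gene Nppb at 887 ± 184 and 965 ± 308 CPM, on soft and stiff respectively. The log2 fold changes of these genes lay between -0.12 for Actc1 and 0.20 for Ttn, and none passed the test. Soft 4 had the highest level of the soft libraries for Nppa, Actc1, Myh6 and Tnnt2, with 10552 CPM of Actc1 and 7425 CPM of Myh6. Without soft 4 the log2 fold changes turned to 0.38 for Myh6, 0.34 for Actc1 and 0.20 for Tnnt2, still not past the test. Ttn turned to -0.06 without stiff 4, Myh7 to -0.08 without stiff 3, and Nppb to -0.02 without soft 3 and -0.05 without stiff 2. Nppa kept its sign whichever library was left out.

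**Figure D1:**
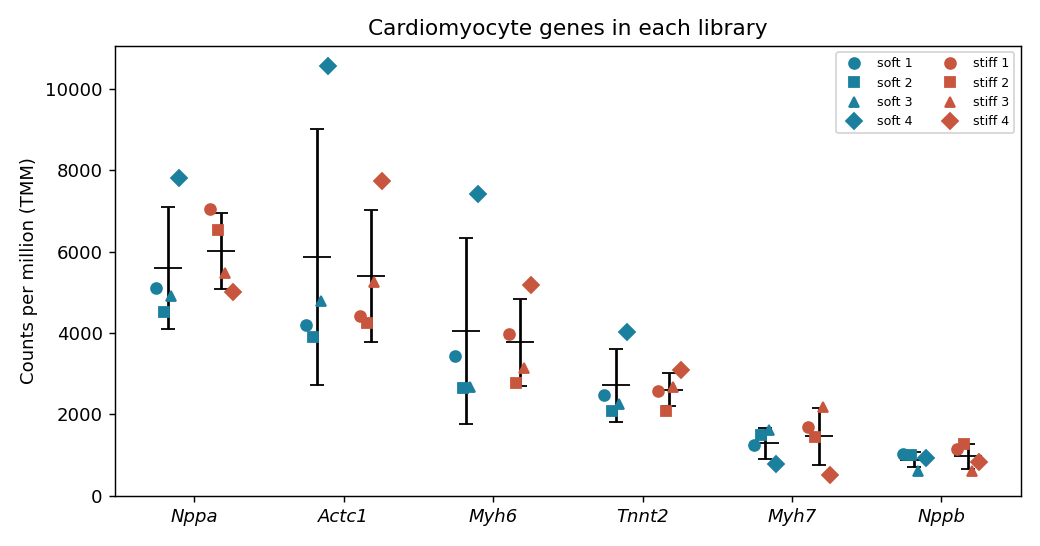
Level of 6 cardiomyocyte genes in CPM (vertical axis, linear from 0) in each of the 8 libraries; symbols mark libraries and black bars the mean ± SD of 4 libraries per substrate. The soft and stiff libraries overlap for each of the 6 genes, and soft 4 lies highest for Actc1 at 10552 CPM.

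Transcripts of other cell types were present on both substrates. The 16 fibroblast markers summed to 14178 ± 3984 CPM on soft and 12251 ± 2376 CPM on stiff (SD, n = 4 each), against 35195 ± 11361 and 34559 ± 6076 CPM for 29 sarcomere genes; the exact permutation p for the fibroblast sum was 0.429. The 11 mural cell markers summed to 3369 ± 684 and 2947 ± 509.7 CPM, the 10 epicardial markers to 1043 ± 205 and 954 ± 119.7 CPM, the 15 endothelial markers to 353 ± 51.1 and 361 ± 71.6 CPM and the 14 leukocyte markers to 158 ± 24.5 and 157 ± 28.0 CPM. Col1a2, a fibrillar collagen gene, was among the most abundant transcripts, with 4796 ± 1240 CPM on soft and 4018 ± 790.4 CPM on stiff. Some of these markers, such as Acta2, are also expressed by immature cardiomyocytes, so the sums do not give cell shares. Haemoglobin genes were listed at 0 in the coding table.

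No coding gene was called between stiff and soft. Of 14059 genes tested by edgeR, 0 rose and 0 fell on stiff, and the lowest adjusted p was 0.99997. At an unadjusted p under 0.05 there were 130 genes (62 higher and 68 lower on stiff), against 703 that chance alone would give. With the number as a replicate block there were 360, also below 703. A count below that of chance means that p-values ran high, in the unpaired test and with the block. The absence of calls therefore does not show that no gene changed. DESeq2 and limma-voom called 0 genes too, with 322 and 181 at an unadjusted p under 0.05. DESeq2 was run without the filter, on a table in which 17351 genes had any count, so its 322 cannot be set against the 703. Some settings with the number as a replicate block, added after the data were seen, did call genes and are given with the dependence on processing. The soft and stiff libraries did not overlap for 181 genes (1.29%), against 2.86% by chance. The median unadjusted 95% interval of a gene reached 1.51-fold to either side of its estimate. It reached 1.35-fold for the 6192 genes at a mean of 32 CPM or more. Most differences smaller than that were not detectable here, and after adjustment many larger ones would be missed too. In counts simulated from these libraries, 50 of 66 changed genes of any level were recovered at 4-fold, 16 of 67 at 2-fold and 2 of 67 at 1.5-fold. Among those at 32 CPM or more, 26 of 26 were recovered at 4-fold, 14 of 19 at 2-fold and 2 of 26 at 1.5-fold. The simulated counts were drawn independently, without variation that the real libraries share across substrates. These shares may therefore overstate what was detectable.

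The lowest p in the coding table belonged to Dhrs3, a retinaldehyde reductase gene at chromosome 4 from 144892534 to 144928209. It stood at 52.7 ± 11.2 CPM on soft and 26.1 ± 4.34 CPM on stiff (SD, n = 4 each), with a log2 fold change of -1.01 (SE 0.23) and no overlap between the substrates; its edgeR adjusted p was 0.99997. Other genes with low p-values were lower on stiff in their means, among them Ogn (osteoglycin, a matrix proteoglycan), with a log2 fold change of -0.66 (SE 0.23), and Spon2 (a secreted matrix protein), with -0.83 (SE 0.30). On the higher side, Cmya5 (a muscle protein of the costamere) had a log2 fold change of 0.53 (SE 0.20), Cdon (a cell surface receptor of muscle differentiation) 0.56 (SE 0.20) and the activin antagonist Fst 0.91 (SE 0.36). These 6 genes were chosen after their values were seen, and none passed the adjustment in the edgeR fit reported here. Apart from Dhrs3 they do not follow the order of p: genes not shown had lower p-values, and the edgeR p of Fst was 0.0248. In settings added after the data were seen, limma-voom with the number as a replicate block called Dhrs3 (adjusted p = 0.00582), Fst (0.0170) and Spon2 (0.0237).

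**Figure D2:**
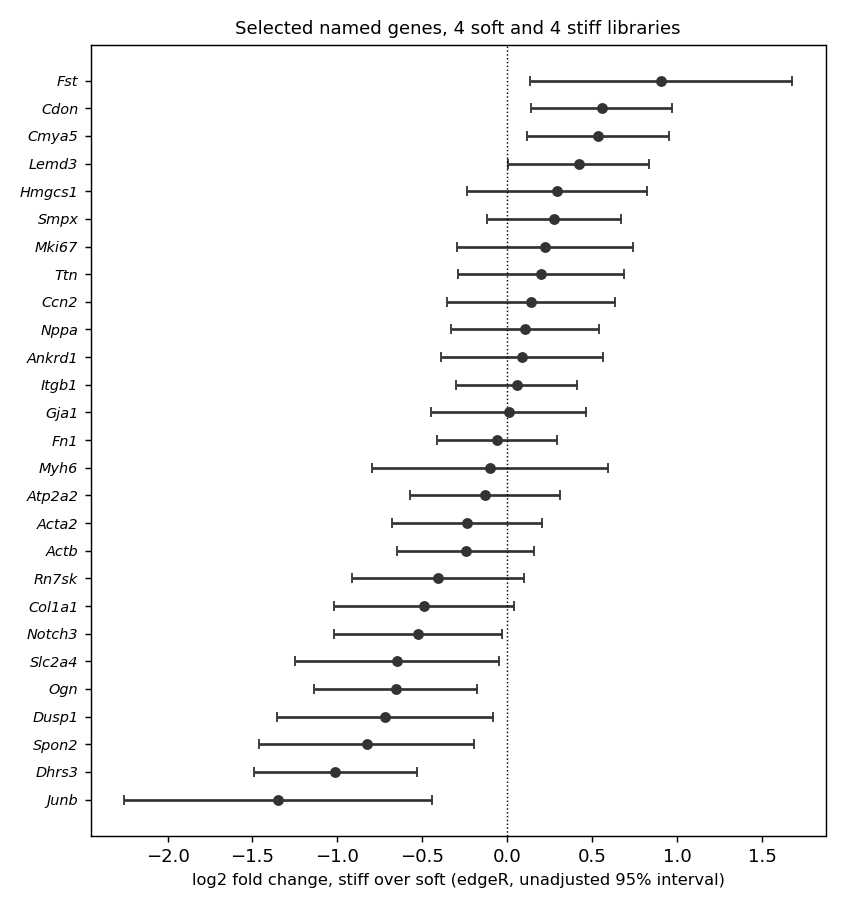
Log2 fold change of stiff over soft (horizontal axis) with the unadjusted 95% interval for 27 named genes (vertical axis), from the edgeR fit of 4 soft and 4 stiff libraries. Junb lies lowest at -1.35 and Dhrs3 next at -1.01, Fst lies highest at 0.91, and the intervals of Myh6, Nppa and Ttn include 0.

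Genes of contraction did not pass the test in either direction. Among 29 sarcomere genes, 13 were higher and 16 lower on stiff in their estimates, with a median log2 fold change of -0.06, a mean difference of 0.04 and a camera adjusted p of 0.627 in the upward direction. Smpx, a small stretch-responsive muscle protein gene, stood at 709 ± 142 CPM on soft and 859 ± 144 CPM on stiff. The sarcomere list was called higher on stiff when soft 4 was left out, with an adjusted p of 7.70e-06, as were oxidative phosphorylation genes, with 0.00339. Neither call held without soft 4 at an estimated correlation, where p was 0.0524 (adjusted 0.787) for the sarcomere and 0.122 (adjusted 0.915) for oxidative phosphorylation. For 21 calcium handling genes the median log2 fold change was 0.04 and the adjusted p 0.627; the calcium pump gene Atp2a2 had a log2 fold change of -0.13 (SE 0.21) and the release channel gene Ryr2 0.10 (SE 0.22). Of 22 ion channel and gap junction genes, 16 had lower estimates on stiff (adjusted p = 0.362). In this list the potassium channel gene Kcnd2 had a log2 fold change of -1.05 (SE 0.47), and Gja1, the main ventricular connexin gene, 0.01 (SE 0.22). The adjusted p was 0.760 for 22 cardiac transcription factors and 0.846 for 15 hypertrophic stress genes, in which Ankrd1 stood at 4971 ± 1270 CPM on soft and 5279 ± 1253 CPM on stiff, and Gdf15 had a log2 fold change of -0.70 (SE 0.40). In each list of this paragraph, 0 members passed when adjusted over all genes and 0 when adjusted over the list alone.

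Genes tied to matrix and mechanical signalling did not pass either. The 40 extracellular matrix genes split into 18 higher and 22 lower estimates on stiff, with a median of -0.03 and an adjusted p of 0.760. Thbs1 stood at 5174 ± 826 CPM on soft and 5529 ± 1323 CPM on stiff, fibronectin (Fn1) at 3775 ± 395 and 3621 ± 271 CPM, Col1a1 had a log2 fold change of -0.49 (SE 0.25) and the crosslinking enzyme gene Loxl1 -0.44 (SE 0.26). Of 33 focal adhesion genes 22 had lower estimates (adjusted p = 0.362); Itgb1, the main beta integrin gene, had a log2 fold change of 0.05 (SE 0.17) and Bcar1 -0.34 (SE 0.23). Targets of YAP and TEAD, the transcriptional effectors of the Hippo pathway, had 7 higher and 14 lower estimates (adjusted p = 0.627), with Ccn2 at 0.14 (SE 0.23) and Amotl2 at -0.23 (SE 0.19). Targets of the actin-regulated factor SRF had 22 of 26 lower estimates, a median of -0.16 and an adjusted p of 0.127; Actb was at -0.25 (SE 0.19) and Acta2 at -0.24 (SE 0.21). The SRF list passed with limma-voom (adjusted p = 0.0225), without soft 1 (0.00286) and without stiff 3 (0.0380), and with an estimated correlation its p was 0.214 and its adjusted p was 0.988. TGF-beta targets had an adjusted p of 0.627, with Ltbp3, a binding protein of latent TGF-beta, at -0.41 (SE 0.18). Adjusted over the list alone, 0 members of these 5 lists passed.

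The other lists were tested in the same way. Camera adjusted p-values were 0.127 for 81 ribosomal protein genes (62 lower on stiff, Rplp1 at a log2 fold change of -0.54), 0.311 for 20 cholesterol synthesis genes (15 higher, Hmgcs1 at 0.29), 0.311 for 18 nuclear envelope genes (14 higher, Lemd3 at 0.42), 0.311 for 22 immediate early genes (15 lower), 0.362 for 23 glycolysis genes (18 lower, the glucose transporter gene Slc2a4 at -0.65) and 0.362 for 16 hypoxia genes (13 lower). Junb and Dusp1, of the immediate early list, stood at 25.3 ± 19.9 and 30.2 ± 10.0 CPM on soft and at 9.93 ± 2.35 and 18.3 ± 5.98 CPM on stiff. Soft 4 held 54.7 CPM of Junb against 12.3 to 19.9 CPM in the other soft libraries, and without it the log2 fold change of Junb went from -1.35 to -0.63. For the remaining lists they were 0.657 for 40 cell cycle genes (Mki67 at 0.22, Top2a at 0.10), 0.627 for chromatin modifiers, 0.642 for p53 targets, 0.950 for fatty acid oxidation (median -0.02) and 0.957 for oxidative phosphorylation (median -0.02). They were 0.950 for heat shock and unfolded protein response genes, 0.906 for interferon response and 0.719 for named noncoding RNAs of the coding table (long ones plus the structured RNAs Rn7sk and Rmrp). Among cell type markers they were 0.550 for fibroblasts, 0.846 for endothelium (Flt1 at 0.11), 0.950 for leukocytes (median -0.09) and 0.760 for epicardium (Krt18 at -0.38). In fatty acid oxidation, oxidative phosphorylation and leukocyte genes the camera direction was up although the median was below 0. Adjusted over the list alone, 0 members of any of these lists passed. Leaving out soft 1 gave adjusted p-values under 0.05 for immediate early (0.0285), glycolysis (0.0224), hypoxia (3.35e-04) and cholesterol genes (8.29e-04). The list was called without soft 2 (0.00824), stiff 2 (0.0241) or stiff 3 (0.0380) for ribosomal proteins, without stiff 1 (0.0111) for the cell cycle, without stiff 3 (0.0380) for hypoxia, and without stiff 4 for immediate early (0.0293) and cholesterol genes (0.00114). With an estimated correlation and any 1 library left out, 0 lists were called, and the lowest adjusted p was 0.648. The mitochondrially encoded and erythroid lists had 0 tested members, and 3 others had under 5: markers of nerve-associated cells, sex-linked genes and hosts of small nucleolar RNAs.

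Replication-dependent histone genes, which encode the histones made in S phase, were called lower on stiff as a list. Of 48 tested members 46 had lower estimates, with a median log2 fold change of -1.21 and a camera adjusted p of 7.31e-06 at the preset correlation of 0.01. The estimated correlation between members was 0.678. With it the call was lost, with a camera p of 0.316 and an adjusted p of 0.988. With fry the p was 0.429, and the exact permutation p of the library score was 0.371. Hist1h4d stood at 34.0 ± 33.3 CPM on soft and 11.9 ± 5.20 CPM on stiff, and Hist4h4 at 7.74 ± 4.80 and 2.76 ± 2.35 CPM. Hist2h2be went the other way, with 2.50 ± 0.46 CPM on soft and 6.53 ± 1.62 CPM on stiff, and the most abundant member that the rule named, Hist1h1c, had 127 ± 72.0 and 91.9 ± 7.28 CPM. None of the 48 passed adjusted over all genes, and 0 passed adjusted over the list alone. Soft 4 had the highest library score, 2.02 on the log2 scale, followed by soft 3 at 1.06, and without soft 4 the adjusted p was 0.482. The log2 fold change went from -1.51 to -0.58 for Hist1h4d and from -0.47 to 0.01 for Hist1h1c when soft 4 was left out, and from -1.48 to -2.27 for Hist4h4 when stiff 3 was left out. Soft 4 also had the highest share of small structured RNAs, at 0.889% of counts against 0.366% to 0.673% in the other soft libraries. Members of this family are near-identical in sequence, so that counts of single genes are uncertain, and reads from the H2B part of the transgene were not separated.

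Markers of smooth muscle and pericytes were the other list called lower on stiff. All 11 members had lower estimates, with a median log2 fold change of -0.16, a mean library score difference of -0.47 and a camera adjusted p of 0.0428; with an estimated correlation p was 0.106 and the adjusted p was 0.988. Notch3, a receptor of mural cells, stood at 42.9 ± 9.45 CPM on soft and 29.9 ± 6.62 CPM on stiff, and Tagln, an actin-binding protein gene of smooth muscle, at 886 ± 178 and 791 ± 228 CPM. Smooth muscle myosin (Myh11) had a log2 fold change of -0.62 (SE 0.39). The list shares Acta2, Tagln and Cnn1 with the SRF targets. None passed adjusted over all genes, and 0 adjusted over the list alone. The library score was 0.53 in soft 3 and 0.56 in soft 4, 0.15 in soft 2 and -0.31 in soft 1, against -0.28 to -0.20 in the 4 stiff libraries (exact permutation p = 0.143). The call was lost when soft 2 (adjusted p = 0.0554), soft 3 (0.247), soft 4 (0.320), stiff 1 (0.129), stiff 2 (0.0944) or stiff 4 (0.183) was left out.

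**Figure D3:**
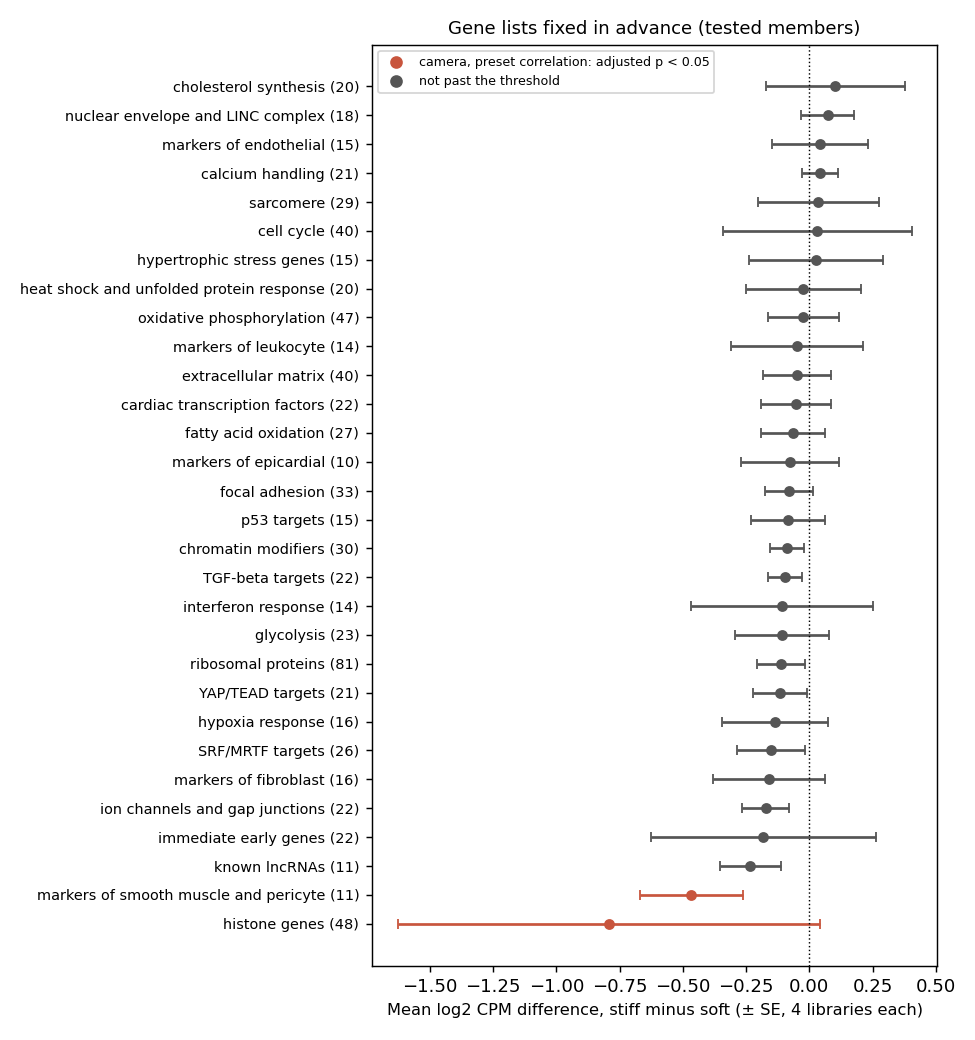
Mean difference of log2 CPM between stiff and soft (horizontal axis, ± SE over 4 libraries each) for the 30 tested gene lists (vertical axis, tested members in brackets). The 2 lists called by camera at its preset correlation, histone genes at -0.79 and mural markers at -0.47, lie lowest.

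Long noncoding RNAs were measured in a separate table, in which 1 transcript took a large part of the counts. NONMMUG020671 held from 25.4% to 38.5% of noncoding counts per library, with a log2 fold change of -0.12 (SE 0.20). Of 5747 noncoding genes tested by edgeR, 0 rose and 0 fell on stiff, with a lowest adjusted p of 0.99995. At an unadjusted p under 0.05 there were 57, and 91 with the number as a replicate block, against 287 expected by chance. Here too p-values ran high, and the absence of calls does not show that no gene changed. DESeq2 and limma-voom called 0 as well, with 391 and 174 at an unadjusted p under 0.05. DESeq2 was run without the filter, on a table in which 12736 IDs had any count, so its 391 cannot be set against the 287. Among IDs with a low p, NONMMUG019310 stood at 41.4 ± 13.9 CPM of the noncoding table on soft and 118 ± 58.6 on stiff (95% interval of the log2 fold change 0.54 to 2.47). NONMMUG026002 stood at 106 ± 57.3 and 36.6 ± 24.0 CPM (log2 fold change -1.53, SE 0.54). These 3 IDs were chosen after their values were seen. The median 95% interval reached 4.14-fold to either side, so differences below that were mostly not detectable. Larger ones could be missed too, since 13 of 66 simulated noncoding genes changed 4-fold were recovered. In the coding table, the imprinted long noncoding RNA H19 stood at 750.4 ± 443 CPM on soft and 747 ± 439 CPM on stiff. Among structured RNAs of that table, which are not long noncoding RNAs, the small nuclear RNA Rn7sk stood at 4811 ± 1531 and 3630.1 ± 897 CPM. Rmrp, the RNA part of a ribonuclease, stood at 431 ± 365 and 159 ± 108 CPM. The log2 fold change of Rmrp went from -1.43 to -0.70 without soft 4 and to -2.02 without stiff 3.

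The libraries did not separate by substrate. Correlations of log2 CPM over the tested coding genes averaged 0.911 within a substrate (range 0.883 to 0.936). Between substrates they averaged 0.911 for libraries of different number and 0.928 for libraries of the same number. These correlations are across genes, which are not independent replicates. The first principal component held 27.4% of the variance and set stiff 3 (117.7) apart from the other 7 libraries (-34.3 to 6.91). Stiff 3 had 13931 coding genes detected against 14697 to 15292 in the others, and 712 tested genes at 0 counts against 146 to 295. Over the 6192 genes at 32 CPM or more, the first component held 44.7% and soft 4 lay farthest out, at 30.3. Without soft 4 and stiff 3, a setting chosen after the data were seen, edgeR called 0 coding and 0 noncoding genes.

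**Figure D4:**
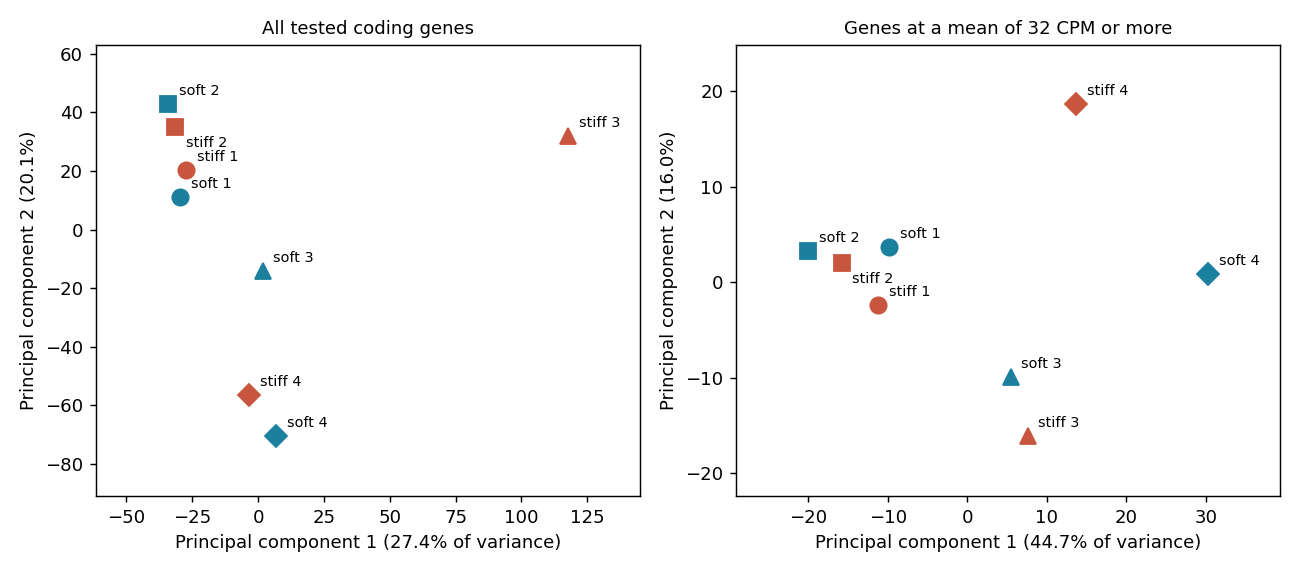
Principal components 1 and 2 of log2 CPM (axes, with the share of variance) for the 8 libraries, over 14059 tested coding genes (left) and 6192 genes at a mean of 32 CPM or more (right). Color marks the substrate and the symbol the last digit of the library code; stiff 3 lies apart in the left panel at 117.7 on component 1, and neither panel separates the substrates.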

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

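The comparison of other library splits for the gene lists was planned; the other tests in this part were chosen after the results were seen. A library was singled out where it lay far from the other 3 of its substrate by Dixon's ratio (critical value 0.829). This happened in 13 of 208 groups of 4 values, where chance singles out about 1 in 20, or 10.4. Of the 13, 5 concerned soft 4: Actc1 (10552 CPM, others 3905 to 4796), Myh6 (7425 CPM, others 2634 to 3432), Ier2, an immediate early gene (40.2 CPM, others 2.64 to 7.83), Hist1h1c (235 CPM, others 87.4 to 93.6) and the sarcomere list score (0.65, others -0.33 to -0.20). Stiff 4 also stood out for Ier2 (15.7 CPM, others 1.87 to 3.06), for Cmya5 (167 CPM, others 121 to 128) and for a low share of counts in ribosomal protein genes (0.723%, others 0.940% to 0.976%). Stiff 3 stood out for tested genes at 0 counts (712, others 159 to 246), Rplp1 (115 CPM, others 73.7 to 79.7) and Rmrp (319 CPM, others 92.0 to 129). Soft 1 stood out for the macrophage gene Lyz2 (145 CPM, others 73.3 to 83.7) and for a low hypoxia list score (-0.47, others 0.21 to 0.31).

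The counts of calls between substrates were set against the 35 splits of the 8 libraries into 4 and 4. The real split gave 0 coding genes with edgeR (130 at an unadjusted p under 0.05; DESeq2 and limma-voom 0), and the highest other gave 887. It gave 0 noncoding genes (57 at an unadjusted p under 0.05; DESeq2 and limma-voom 0), and the highest other gave 18. With a real count of 0, 35 of 35 splits give as many by construction, so that this share decides nothing for either table. At an unadjusted p under 0.05, 34 of the 35 splits gave at least the 130 coding genes of the real one. For gene lists, 34 of 35 splits gave as many as the real 2 or more, and the highest gave 14. Chance can therefore not be excluded for the lists or for the 130 genes, and camera at its preset correlation called at least 1 list in each of the 35 splits. The split with 887 coding and 18 noncoding calls put soft 1, soft 2, stiff 1 and stiff 2 against the other 4 libraries, which points to a structure of the samples that runs across the substrates. Such a structure can raise the counts of other splits, while the real split is balanced over it. The comparison with other splits therefore does not measure chance alone.

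For the lower histone genes on stiff, the pattern with the smallest list p, whether soft 4 alone accounts for the call remains open. Without it the adjusted p was 0.482 and the mean score difference went from -0.79 to -0.25 (SE 0.78), but the list was still called when stiff 3 was left out as well (0.00199, but 0.888 with an estimated correlation). A different yield of RNA without a poly(A) tail, which most but not all transcripts of such histone genes lack, remains open. The 34 small structured RNAs were lower in mean on stiff too (mean log2 difference -0.48, SE 0.24, exact permutation p = 0.0857). Yet over the 8 libraries centred on their substrate the correlation with the histone score was r = 0.109 (permutation p = 0.798, rho = 0.167, p = 0.703) and 0.513 without stiff 3 and stiff 4. Fewer cells in S phase on stiff, the biological explanation, also remains open, because no label pairs the libraries. Unpaired, the 15 other S-phase genes differed by 0.0122 on the log2 scale with an SE of 0.47. The histone and S-phase scores moved together between libraries (r = 0.867 over the 8 libraries). The histone score minus the S-phase score of each library, which needs no pairing, differed by -0.81 (SE 0.43, exact permutation p = 0.143). If equal numbers were pairs, the S-phase difference would have an SE of 0.12, and would then argue against this explanation. Reads shared within the histone family were not tested.

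Library stiff 3 lay apart from the rest in the principal components. Shallow sequencing is argued against by its total of 32412633 coding counts, above the median of the 8 libraries. Low capture of rare transcripts in that library is a candidate explanation: its mean correlation with the others was the lowest over all tested genes (0.889) but ranked 4 from the lowest over genes at 32 CPM or more (0.929). No biological explanation was tested for it.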

How the results depend on the processing

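The number of coding genes called was 0 under each alternative fixed in advance that was run, and so was that of noncoding genes (edgeR as reported: 130 and 57 at an unadjusted p under 0.05); settings added after seeing the data moved the coding count. The labels do not pair the libraries, but with the number as a replicate block edgeR called 0 coding genes (lowest adjusted p 0.346, 360 at an unadjusted p under 0.05) and 0 noncoding genes, with 3 lists called: histone (adjusted p = 8.69e-14), mural (0.0324) and SRF (0.0324). With the block and an estimated correlation 0 lists were called, and the adjusted p was 0.862 for each of these 3. Adjusted over the list alone, 3 immediate early genes and 1 histone gene passed with the block, against 0 in the reported fit. In the same fit limited to genes at 8 CPM or more, 3 genes were called (Adam22 and Dhrs3 lower, Fst higher, adjusted p = 0.0186), while DESeq2 with the block called 0. Limma-voom with the block called 8: Dhrs3 (adjusted p = 0.00582), Hist1h4d (5.34e-04), Junb (0.0197), Rmrp (4.03e-14), Rpph1 (1.12e-07) and Spon2 (0.0237) lower, and Fst (0.0170) and Lars2 (8.35e-11) higher. As a hint from the data, deviations from the substrate means correlated at 0.104 to 0.305 between libraries of the same number (other numbers -0.06 on average), and 6 of 8 libraries correlated best with their own number. Over coding genes at 32 CPM or more these values were 0.305 to 0.515 (other numbers -0.13) and 7 of 8, and in the noncoding table -0.01 to 0.08 and 2 of 8. If equal numbers were pairs, the S-phase difference of stiff minus soft would be 0.0122 with an SE of 0.12, against 0.47 unpaired, and that of the histone score -0.79 with an SE of 0.37.

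Against 2 lists in the reported test, 1 list was called with no filter or with both tables joined, 0 with an estimated correlation, 0 with fry, 4 with the replicate block without number 4, and 1 to 7 with a library left out. The histone list's adjusted p was 0.988 with an estimated correlation, 0.980 with fry 4.21e-13 to 0.482 with a library left out, 0.00199 without soft 4 and stiff 3, and 1.66e-04 with the replicate block without number 4. That of the mural list was 0.0970 with no filter, 0.0941 with joined tables, 0.988 with an estimated correlation, 0.980 with fry, 0.185 without soft 4 and stiff 3, 0.501 with the replicate block without number 4, and 9.87e-04 to 0.320 with a library left out. With an estimated correlation 0 lists were called under any of these. The adjusted p of both lists was then 0.960 without soft 2, 0.987 without soft 3, 0.918 without soft 4, 0.986, 0.996, 0.849 and 0.988 without stiff 1 to 4, 0.888 without soft 4 and stiff 3, and 0.811 with the block without number 4. Without soft 1 it was 0.818 for histone and 0.648 for mural genes. The cause of these changes was not tested. Of 62 named genes, 24 changed sign in at least 1 alternative (61 of 1354 values), none while called. Not run were the fit without mitochondrially encoded and haemoglobin genes, which removes no tested gene, and DESeq2 and the fold test for lists, which give no list values here. The noncoding table holds 6.66 to 8.63 counts per 100 coding counts, which limits its precision.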

Other observations

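The test of retinoid genes in this part was set before its result was seen; the other tests were chosen after. Several gene groups differed between libraries across the substrates. The cell cycle list score lay between -0.53 and -0.39 in soft 1, soft 2, stiff 1 and stiff 2, and between 0.35 and 0.51 in soft 3, soft 4, stiff 3 and stiff 4. The histone list score was below 0 in the former 4 libraries (-1.19 to -0.42) and above 0 in the latter (0.18 to 2.02). Y-linked genes went the other way, with Ddx3y at 263, 390, 218 and 382 CPM in soft 1, soft 2, stiff 1 and stiff 2 and at 84.4, 94.96, 83.7 and 153 CPM in soft 3, soft 4, stiff 3 and stiff 4. H19 was lowest in soft 4 (238 CPM) and stiff 4 (148 CPM) and highest in soft 3 (1293 CPM) and stiff 3 (1162 CPM). No label groups these libraries. The split of soft 1, soft 2, stiff 1 and stiff 2 against the others is the one that gave 887 coding and 18 noncoding calls above, and 14 lists. It was noticed in these same data, so no separate test of the values in this paragraph is given.

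Libraries whose codes end in the same digit varied together across the substrates in the coding table. Of the 24 ways to pair each soft with a stiff library, the pairing by last digit had the highest mean correlation of deviations from the substrate means (0.18, the next 0.17), so that 1 of 24 was as high, a share of 0.0417 that is the smallest 24 pairings can give. Without Y-linked genes and Xist, of which 4 were tested, the mean was also 0.18. So few of 14059 tested genes could hardly move it, so this decides nothing about the sex mix. Over coding genes at 32 CPM or more, deviations correlated at 0.305 to 0.515 by last digit, and 7 of 8 libraries correlated best with their own digit. The noncoding table did not show this: its deviations correlated at -0.01 to 0.08 by last digit, and 2 of 8 libraries correlated best with their own digit. Sequencing depth shared by the last digit is argued against, since 16 of 24 pairings had as small a difference in total counts. A pool of embryos shared by both substrates is a candidate explanation that the sex mix of the embryos leaves open: 2 of 24 pairings had as small a difference in Y-linked genes as the one by last digit. Whether the digit marks a litter, a day or a sequencing batch is not given in the sources used here.

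Dhrs3, which had the lowest p of the coding table, is induced by retinoic acid in many tissues, and lower retinoic acid signalling on stiff may be behind its lower level. For 12 tested retinoid genes other than Dhrs3, the mean log2 difference was -0.23 (SE 0.17, exact permutation p = 0.286), and camera gave p = 0.534 for the list. The test left the hypothesis open.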
